A study of Mus musculus with 27 samples.

How the data were processed

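Hematopoietic stem cells (HSC) and hematopoietic progenitor cells (HPC) of mice on the B6 background were profiled per the labels at embryonic day 16.5 (fetal) and at 8 weeks of age (adult). The assay was ChIPmentation, in which chromatin bound by an antibody against a histone mark is tagged by the Tn5 transposase before sequencing. The labels described 27 libraries, of which 24 fell into 8 groups by age, cell type and mark, and 3 were input libraries. H3K4me1 was profiled in HSC and HPC, and H3K27ac in HPC. A second K27 set in HPC carried conflicting labels, with H3K27me3 in its titles and H3K27ac in its mark field, and is called the second K27 set throughout.

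Reads were aligned with Novoalign and peaks were called with MACS2 on mm10 (GRCm38), per the submitters' processing notes, and the versions of both tools are not given in the sources used here. The authors gave 1 filtered peak list per group, pooled over the libraries of that group. The filter, the calling threshold and the role of the input libraries in calling are not given in the sources used here. In each list the authors wrote a ratio or fold of the ChIP signal over background at each peak, as MACS2 writes it. The authors' −log10 p and −log10 q values of each peak stood beside it. These values belong to each peak and its own list, so they were used only to describe, rank or filter sites within a list and were not compared between lists. Peak numbers left in the names showed what the filter removed. Between 92.4% and 99.995% of the first 20000 numbers of a list had been kept, against 0.375% to 30.0% of its last 20000 numbers. Signal tracks and reads were not used here, and the read depth of each library is unknown.

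The sample groups, gene lists, comparisons, naming rule and most alternatives were fixed before the data were examined. A site was a peak interval, since 0 peaks overlapped another peak of the same list. The main comparisons used the strongest 20000 sites of each list by −log10 p. A site was called age-only when it overlapped no peak of the other age's full list by 1 bp or more, and otherwise shared. The same rule with cell type in place of age gave HSC-only and HPC-only sites. Lack of a called peak is not lack of the mark, because calling depends on depth and list length. Shares carry 95% Wilson intervals, and differences between shares carry Newcombe intervals. These intervals cover counting error only, because the libraries of a group were pooled and no spread between replicates can be measured. For the same reason no test across samples was run and no p-value is given. Chance overlap came from 100 circular shifts of the sites along their chromosomes with a fixed seed.

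Each site was assigned to the nearest of 21887 protein-coding genes of the RefSeq table for GRCm38 within 100 kb of the gene body, at distance 0 inside a gene. The plan had named the nearest transcription start and promoters. The gene table used here gave gene starts and ends without strand or exons, so gene bodies stood in for starts and the area within 1 kb of either gene end stood in for promoters. Exons, introns and sequence motifs were not analysed here, because no genome sequence or transcript table was used.

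The 19 fixed gene lists covered a fetal stem cell programme, imprinted growth regulators, HSC identity and quiescence, type I interferon and antigen presentation, lymphoid priming, myeloid genes, erythroid and megakaryocyte genes, cell cycle, immediate early and AP-1 genes, inflammatory signalling, Hox clusters A and B, housekeeping genes and silent developmental regulators. The remaining lists held markers of other cells, namely hepatocytes, endothelium, B cells, T and NK cells, macrophages and stroma. Of the 440 names in these lists, 6 were not matched to the gene table. For each list the difference between fetal-only and adult-only sites at its members was placed among 10000 random lists matched on the number of strongest sites per gene. The resulting percentile describes the pooled lists and is not a p-value. Per comparison, 0.95 of the 19 lists would lie outside the central 95% of random lists by chance. Simulated data for H3K27ac, described below, gave a higher rate, of 1.61 lists. By number of sites, 1 or 2 lists lay outside in every comparison, near these numbers. The naming rule took, per age comparison and direction, the 6 genes with the most age-only sites, up to 3 members of every fixed list with the most, and the 2 strongest sites, and not every list member it took is printed. Genes named for the HSC and HPC comparison, Igf2bp1 and Igf2bp2 for H3K27ac, and Igf2bp1, Igf2bp2 and Igf2bp3 for the second K27 set fall outside this rule and were chosen after their values were seen.

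The pipeline was tested on simulated data. An age-only share set at 3% of the strongest 20000 in a list of 177310 sites came back as 3%. The sites had been deleted from a copy of the same list, so this checked the counting only. Of 200 random gene lists, 8.5% fell outside the central 95%. A list planted with added fetal-only sites reached percentile 97.2, just under the upper limit of 97.5, so the planted effect was missed. Alternatives changed the overlap rule, the number and ranking of sites, the −log10 q filter, list length, the gene assignment, merging of nearby peaks and the use of chromosome X. Of these, 3 were chosen after seeing the data, namely leaving out sites of low fold, counting list members in place of sites, and trimming all 4 H3K4me1 lists to the shortest. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.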

Results

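Histone marks were mapped in mouse blood stem and progenitor cells before and after birth. H3K4me1 marks enhancers and the flanks of promoters, H3K27ac marks active enhancers and promoters, and H3K27me3 is the mark that Polycomb places on silent genes. The H3K4me1 lists pooled 3 fetal HSC, 4 adult HSC, 3 fetal HPC and 3 adult HPC libraries. The H3K27ac lists of HPC pooled 3 libraries at each age, and the second K27 set pooled 2 fetal and 3 adult HPC libraries. H3K4me1 gave 231188 sites over 176 Mb in fetal HSC, 143571 over 155 Mb in adult HSC, 177310 over 200.2 Mb in fetal HPC and 126502 over 176 Mb in adult HPC. H3K27ac gave 50858 sites over 45.0 Mb in fetal HPC and 63108 over 71.8 Mb in adult HPC. The second K27 set gave 54339 sites over 41.3 Mb in fetal HPC and 54293 over 26.6 Mb in adult HPC. Of these, 7097 fetal and 576 adult sites had a −log10 q of at least 5. Library depth is unknown, and with 1 pooled list per group there are no replicate values.

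In HSC, fetal-only H3K4me1 sites were most numerous at Calcrl, a receptor subunit for adrenomedullin, with 6 sites. Foxp1, a forkhead transcription factor, Mecom, a transcription factor needed by HSC, and Hmga2, a chromatin protein of fetal HSC, had 4 fetal-only sites each, and Csnk1g3 and Tenm4 had 3 each. Adult-only sites numbered 3 each at Fcgr3, an activating Fc receptor of myeloid cells, Scara5, a ferritin receptor, Sulf2, a heparan sulfatase, Sh2b2 and Ntng2. The question addressed was which enhancer-type chromatin differs between fetal and adult stem cells.

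Of the strongest 20000 HSC sites, 609 (3.04%, 2.82 to 3.29) were fetal-only and 426 (2.13%, 1.94 to 2.34) were adult-only, against chance shares of 85.1% and 80.5%. The fetal-only share was higher by 0.915 percentage points (0.604 to 1.23). The fetal stem cell programme held 6 fetal-only and 0 adult-only sites, at percentile 99.9 of matched random lists. Its fetal-only sites lay at Hmga2, at Lin28b, the RNA-binding protein that drives fetal blood formation, with 1 site (fold 6.18), and at Igf2bp1, an RNA-binding protein of the same programme, with 1 site (fold 5.65). Near gene ends the full lists ran the other way. A peak lay within 1 kb of a gene end at 8 of its 12 members in fetal HSC and 12 in adult HSC. In HPC the counts were 6 and 12. Over all coding genes the HSC shares were 62.7% and 67.6%. HSC identity genes held 5 fetal-only and 0 adult-only sites, 4 at Mecom and 1 at Erg, an ETS factor, and stayed inside the random range at percentile 83.9. Myeloid genes held 0 fetal-only and 3 adult-only sites, all at Fcgr3, at percentile 2.13. Counted by members, this myeloid list moved inside the range, to percentile 14.1. The other 16 lists lay inside the central 95% and held at most 2 sites in either direction. Among them, lymphoid priming had fetal-only sites at Tcf7 and Rora, and the silent developmental regulators had adult-only sites at Hoxd9 and Hoxd13.

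The strongest fetal-only HSC site with a high fold lay inside Foxp1 on chromosome 6, from 99208593 to 99209612 (mm10), with fold 11.6. A site on chromosome 9, from 3023463 to 3023619, ranked above it by −log10 p with a fold of 1.43 and had no gene within 100 kb. The strongest adult-only site lay on chromosome 18 from 56303431 to 56303574 (fold 3.91), 83982 bp from Gramd3. The next lay inside Cntnap5c on chromosome 17 from 57855977 to 57856176 (fold 4.35). They were only 144 and 200 bp wide and were also the strongest adult HSC sites without an H3K4me1 peak in adult HPC. Whether such narrow sites are artifacts was not tested. Sfi1 had 4 adult-only sites, but with a highest fold of 3.19. The order of the fetal and adult shares depended on list length, since the difference turned to -2.28 points with both lists at the same number of sites and was 20.1 points over all sites. The fetal stem cell programme stayed outside the random range in 11 of 14 alternatives, with a lowest percentile of 78.5 when peaks within 1 kb were merged, and the myeloid list in 7 of 14.

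In HPC, H3K4me1 differed between ages at fewer of the strongest sites than in HSC, and its adult-only sites at myeloid genes lay mostly at 1 gene. Fcgr3 had 4 of them with a highest fold of 10.2, and Cebpb, a transcription factor of granulocytes and macrophages, had 1 (fold 5.84). Nlrc5 and Ciita, the transactivators of MHC class I and class II genes, had 1 adult-only site each, with folds of 6.10 and 5.99. On the fetal side, Lin28b had 1 fetal-only site with fold 6.59, and Prdm16 and Fli1, transcription factors of HSC, had 1 each.

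Fetal-only sites numbered 263 of 20000 (1.31%, 1.17 to 1.48) and adult-only sites 303 (1.51%, 1.35 to 1.69). The difference of -0.200 points (-0.433 to 0.032) lay within counting error. Chance shares were 82.6% and 79.9%. Myeloid genes held 0 fetal-only and 5 adult-only sites, at percentile 0.355, the only list outside the central 95% by number of sites. Interferon and antigen presentation genes held 0 and 3, at Nlrc5, Ciita and H2-Q7, at percentile 2.90, and counted by members they lay outside the random range at 1.29. H2-Q7 is 1 of a family of near-identical genes whose reads can be shared. The fetal stem cell programme held 1 and 0 (percentile 91.0), HSC identity 2 and 0 (percentile 83.9) and macrophage markers 1 and 0, at Marco (percentile 97.3). Inflammatory signalling held 0 and 1, at Il1b.

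The genes with most fetal-only HPC sites had 2 each, at Mctp2, Mtap, Emsy, Efcab5, Tshz2 and Adk. Adult-only sites numbered 3 each at Mras, a small GTPase, and Nrg2, a growth factor, and 2 each at Wnt9a and Nav2. The strongest fetal-only site lay inside Cntrl on chromosome 2 from 35116631 to 35120735 (fold 9.21), and the next on chromosome 15 from 39976925 to 39978827 (fold 8.77), 33860 bp from Lrp12. The strongest adult-only site lay inside Fcgr3 on chromosome 1 from 171065196 to 171065514. The next, on chromosome 17 from 3081433 to 3082055 near Scaf8, had a fold of 3.08, under its list's median of 3.22. Sfi1 again had adult-only sites of low fold, 5 with a highest fold of 2.81. Across alternatives the difference between the shares ran from -1.46 points at equal list length to 17.2 points over all sites, where Rasgrf1, with 1 fetal-only site here, had more adult-only sites. The myeloid list stayed outside the random range in 12 of 14 alternatives and moved inside with peaks merged (percentile 18.4) and counted by members (3.92).

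Fetal progenitors had H3K27ac sites at genes of the fetal stem cell programme that were not called in adult progenitors. Lin28b had 3 fetal-only sites (highest fold 14.3), Igf2bp3 2 (8.37), Hmga2 2 (3.85), Igf2bp2 1 (9.71) and Igf2bp1 1 (7.11). In some of these genes other H3K27ac sites were called in adult HPC. Gene bodies held 18 fetal and 13 adult sites at Hmga2, 12 and 5 at Igf2bp3, and 8 and 8 at Igf2bp2. The bodies of Lin28b and Igf2bp1 held 0 adult sites. Adult progenitors had H3K27ac sites at myeloid genes that were not called in fetal ones. Cebpb had 5 adult-only sites (highest fold 7.88), and Cebpa, the master factor of granulocyte and monocyte fate, had 3 (6.81). The Cebpb gene body itself held 1 H3K27ac site at each age.

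Of the strongest 20000 H3K27ac sites, 1560 (7.80%, 7.44 to 8.18) were fetal-only and 2598 (12.99%, 12.5 to 13.5) adult-only, against chance shares of 94.1% and 94.5%. The difference was -5.19 points (-5.79 to -4.59). It ran from -0.890 points among the strongest 10000 sites of each list to -19.4 points over all sites. These shares were above those of H3K4me1 in HPC, but the strongest 20000 made up 39.3% and 31.7% of the fetal and adult H3K27ac lists and 11.3% and 15.8% of the H3K4me1 lists. Among the strongest 10000 the fetal-only share was 0.42% for H3K27ac and 0.50% for H3K4me1, and the adult-only share 1.31% and 0.76%. Over all sites they were 39.0% and 39.5% fetal-only, and 58.5% and 22.3% adult-only.

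The fetal stem cell programme held 9 fetal-only and 1 adult-only site, at percentile 99.98. Myeloid genes held 1 and 13, at percentile 0.450. Beside Cebpb and Cebpa, Cebpe, a late granulocyte factor, had 1 adult-only site. Among the strongest 10000 sites this list turned, to 1 fetal-only and 0 adult-only sites, and counted by members it moved inside the range, to percentile 4.77. It stayed outside in 10 of 14 alternatives, against 11 of 14 for the fetal programme. Inflammatory signalling held 0 fetal-only and 11 adult-only sites at percentile 2.60, just inside the random range, whose median for this list was a difference of -3. Counted by members it lay outside, at percentile 1.29. They included 2 each at Tnfrsf1b, a TNF receptor, Nfkbia, the inhibitor of NF-kappaB, and Cxcl2, a neutrophil chemokine.

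HSC identity genes held 13 fetal-only and 6 adult-only sites (percentile 90.4). The fetal-only ones included 4 at Prdm16 (highest fold 4.10), 3 at Mllt3, a regulator of HSC self-renewal (4.44), and 2 at Mecom (3.88). Prdm16 also had 1 adult-only site. Imprinted growth regulators held 5 and 4 (percentile 87.6), with fetal-only sites at Peg3 (2, highest fold 8.12), Dlk1 (2, 7.11) and Gnas (1, 9.79). Interferon and antigen presentation genes held 2 and 10 (percentile 11.6), the adult-only ones including 3 at Ly6e, 2 at Nlrc5 and 1 at H2-Q7 (fold 13.9). Lymphoid priming held 4 and 8 (percentile 25.5), with 3 adult-only sites at Dntt, the terminal transferase of lymphoid precursors (highest fold 12.3), and 3 fetal-only sites at Rora. Immediate early genes held 0 and 8 (percentile 13.9), among them Ier3, Nr4a1 and Jun. Cell cycle genes held 0 and 7 (percentile 10.2), 5 of them at Ccnd3, cyclin D3. Housekeeping genes held 0 and 6 (percentile 19.99), and erythroid and megakaryocyte genes 0 and 4 (percentile 21.5), among them Klf1, Tfrc and Itga2b.

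Hox clusters held 2 and 1 H3K27ac sites, fetal-only and adult-only, and the silent developmental regulators 1 and 3. Markers of other cells held few. T and NK cell markers held 0 and 3, at Zap70, Lck and Klrb1c, hepatocyte markers 1 and 3, endothelium 2 and 0, B cells 0 and 1, macrophages 1 and 0, and stroma 0 and 1. All of these lists lay inside the central 95% by number of sites, and T and NK cell markers lay outside by members, at percentile 1.78. With 2 of 19 lists outside, the number was near the 1.61 that the simulated rate gives by chance.

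**Figure D1:**
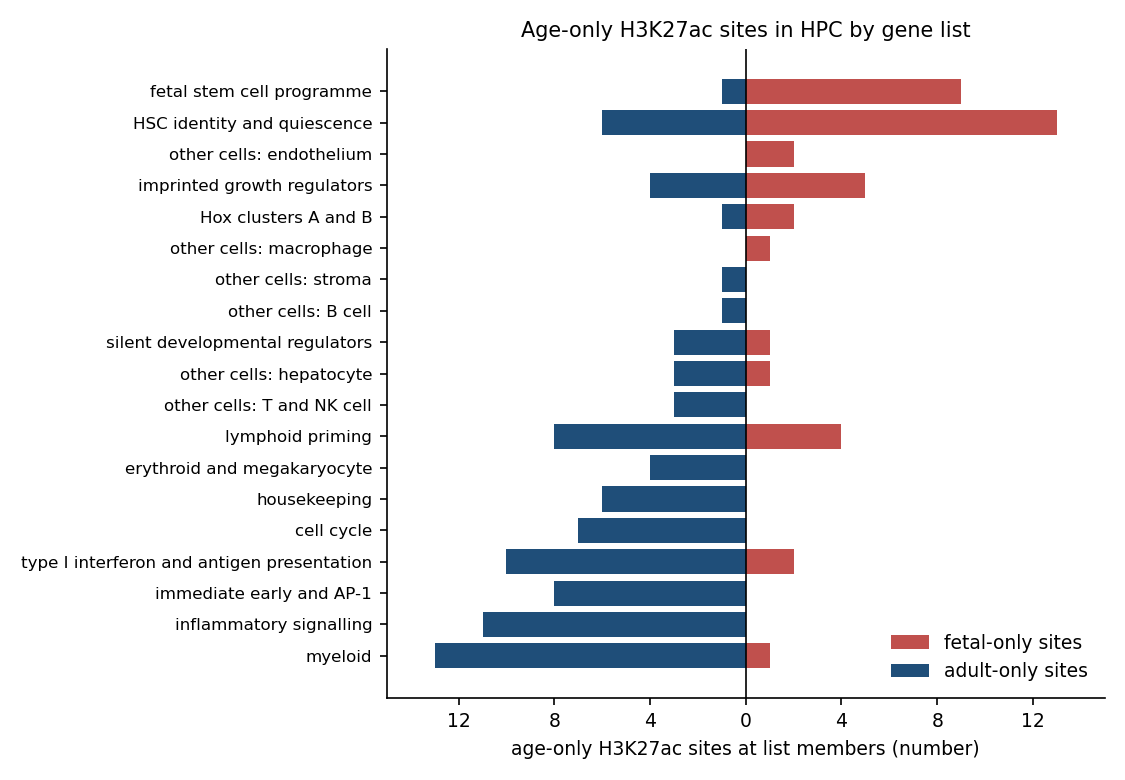
Number of H3K27ac sites in HPC called at 1 age only (horizontal axis) for the members of each of 19 fixed gene lists, with fetal-only sites to the right in red and adult-only sites to the left in blue. The fetal stem cell programme had 9 fetal-only and 1 adult-only site, and myeloid genes had 1 and 13.

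Outside the lists, the most fetal-only H3K27ac sites lay at Ikzf2, the Helios transcription factor, with 8, and Trio, a guanine nucleotide exchange factor, with 7. Rabgap1l, Zfp704, Lrp12 and Tab2 had 5 each. Most adult-only sites lay at Rab11fip4, Cpn2 and Lpp with 6 each, and at Hivep3 and Agap1 with 5 each. With all sites counted, 36899 adult-only against 19858 fetal-only, Zfp704, Dlk1, Prdm16 and Rora had more adult-only than fetal-only sites, a count that was not set against this general excess. The strongest fetal-only site of all lay inside Lin28b on chromosome 10, from 45467081 to 45470948, with fold 14.3. The next lay on chromosome 19 from 61265504 to 61265780 (fold 5.92), 37180 bp from Csf2ra, a subunit of the GM-CSF receptor. Among adult-only sites, the strongest lay on chromosome 18 from 56303414 to 56303578 with a fold of 2.90, under its list's median of 3.19. It was 165 bp wide and lay at the same place as the strongest adult-only H3K4me1 site of HSC. The next lay 5982 bp from Klf9, a Krüppel-like factor, on chromosome 19 from 23133734 to 23136753, with fold 17.7.

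Lin28b, on chromosome 10 from 45376617 to 45486314, had more H3K4me1 and H3K27ac sites in its body in fetal cells and more second-set sites in adult cells. H3K4me1 was called at 24 sites in its body in fetal HSC against 10 in adult HSC, and at 16 in fetal HPC against 3 in adult HPC. H3K27ac was called at 6 sites in fetal HPC and at 0 in adult HPC. The second K27 set had 0 sites in the gene body in fetal HPC and 13 in adult HPC, while sites of both ages lay past the gene end, 4 fetal ones from 45487099 to 45491175 and adult ones from 45487788 to 45499400. At a −log10 q of at least 5, which left 576 adult sites in all, Lin28b had 0 adult-only and 1 fetal-only second-set site.

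**Figure D2:**
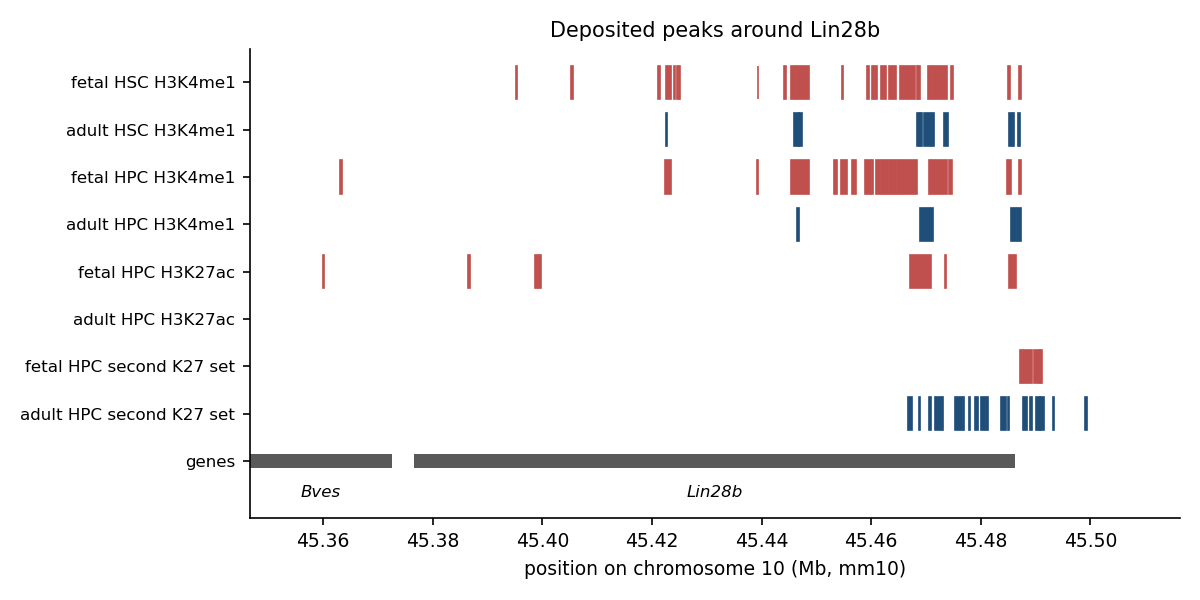
Called peaks around Lin28b along chromosome 10 (horizontal axis, Mb, mm10), with 1 track per pooled list, fetal in red and adult in blue, and genes as grey bars. H3K27ac peaks in the Lin28b body numbered 6 in fetal and 0 in adult HPC, and second K27 set peaks 0 and 13, with peaks of both ages past the gene end.

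The second K27 set lay at silent developmental genes and away from acetylated ones. Of the 55 silent developmental regulators, 51 (92.7%) had a second-set peak within 1 kb of a gene end in fetal HPC and 47 (85.5%) in adult HPC, against 0 and 1 with H3K27ac. Of 40 housekeeping genes, 1 fetal and 0 adult had a second-set peak, against 38 with H3K27ac at each age. The question addressed was which of the conflicting labels the sites resemble. Only 98 of the strongest 20000 fetal sites (0.490%, 0.402 to 0.597) and 3 adult sites (0.015%, 0.0051 to 0.044) overlapped H3K27ac of the same age, below chance shares of 3.67% and 4.11%. Within 1 kb of an H3K27ac peak lay 1.05% and 0.535%. Overlap with H3K4me1 was 12.9% in fetal HPC (chance 13.1%) and 4.70% in adult HPC (chance 9.31%). Over all coding genes, second-set peaks lay at 12.9% of genes in fetal and 9.27% in adult HPC. By these counts the sites resembled the H3K27me3 of the titles, and the values argue against the H3K27ac of the mark field.

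By age, adult-only second-set sites of the fetal stem cell programme numbered 64 against 3 fetal-only, at percentile 0.00, with 30 at Ncam1, a neural cell adhesion molecule, and 20 at Gpc3, a glypican on chromosome X. Lin28b had 5 adult-only and 1 fetal-only site, and Igf2bp1 4, Igf2bp3 3 and Igf2bp2 2 adult-only sites. Sites of 1 gene can be neighbours, as were the 13 adult sites of the full list in the Lin28b body, from 45466774 to 45485145. Such sites are not independent, and the counting intervals do not allow for this. Adult-only sites also lay at the B cell factors Ebf1 (17) and Pax5 (10) and at the B cell kinase Blk (5). Fetal-only sites lay at the imprinted genes Grb10 (7), Rasgrf1 (6) and Dlk1 (4), and at the T cell factor Bcl11b (12).

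Fetal-only second-set sites numbered 8177 of 20000 (40.9%, 40.2 to 41.6) and adult-only sites 7243 (36.2%, 35.6 to 36.9), against chance shares of 97.1% at both ages. The difference was 4.67 points (3.72 to 5.62). Across alternatives the difference ran from 2.28 points for the strongest 10000 to 66.0 points at a −log10 q of at least 5. The fetal stem cell programme was the only list outside the central 95%. With the strongest 20000 sites taken anew from autosomes alone, it held 50 adult-only and 3 fetal-only sites. Counted by members, with chromosome X in use, it moved inside the range, to percentile 3.01. Imprinted growth regulators held 19 fetal-only and 3 adult-only sites (percentile 97.1), HSC identity 9 and 3 (85.4), lymphoid priming 16 and 25 (25.0), B cell markers 1 and 15 (10.1), stroma 7 and 12, and Hox clusters 11 and 5. The silent developmental regulators held 143 and 107 (percentile 84.3), with 11 fetal-only sites each at Lhx2 and Pax3 and 9 at Tbx5. Their adult-only sites included 10 at Pax2. Housekeeping genes held 0 in both directions.

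The genes with most fetal-only second-set sites were Myo16 (34), Nrxn3 (27), Apbb2 (25), Dnah9 (24), Irs2 (22) and Col24a1 (22). Those with most adult-only sites were Frmpd4 on chromosome X (34), Ncam1 and Ankfn1 (30 each), Cacna1e (29), Sdk1 (27) and Asic2 (25). The strongest fetal-only sites lay on chromosome 13 from 92958178 to 92961532 (fold 6.49), 80858 bp from Cmya5, and on chromosome 17 from 36191015 to 36191998 (fold 6.45), 1355 bp from H2-T3. The strongest adult-only sites, on chromosome 7 from 138732983 to 138733924 (fold 6.40) and on chromosome 8 from 107847476 to 107848375 (fold 5.64), had no gene within reach. Of the strongest adult sites, 9026 had a −log10 q under 2, and a −log10 q of at least 5 left 7097 fetal and 576 adult sites, too few adult sites to compare ages gene by gene. The fetal programme then held 7 fetal-only and 0 adult-only sites, inside the random range at percentile 54.6.

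Over all sites, chromosome X held a larger share of the adult second set than of any other list. It carried 6736 of the 54293 adult sites (12.4%, 12.1 to 12.7) and 743 of the 54339 fetal sites (1.37%, 1.27 to 1.47). In the other 6 lists the share ran from 1.12% in fetal H3K27ac to 1.58% in adult HSC H3K4me1. The adult X share was lower among stronger calls, and so was the fetal one. It was 8.09% adult and 0.725% fetal in the strongest 20000, and 2.75% (2.12 to 3.56) adult and 0.2% (0.078 to 0.513) fetal in the strongest 2000. At a −log10 q of at least 5 it was 5 of 576 adult sites (0.868%, 0.371 to 2.02) and 26 of 7097 fetal sites (0.366%, 0.250 to 0.536), with overlapping intervals. The labels name no sex of the animals.

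**Figure D3:**
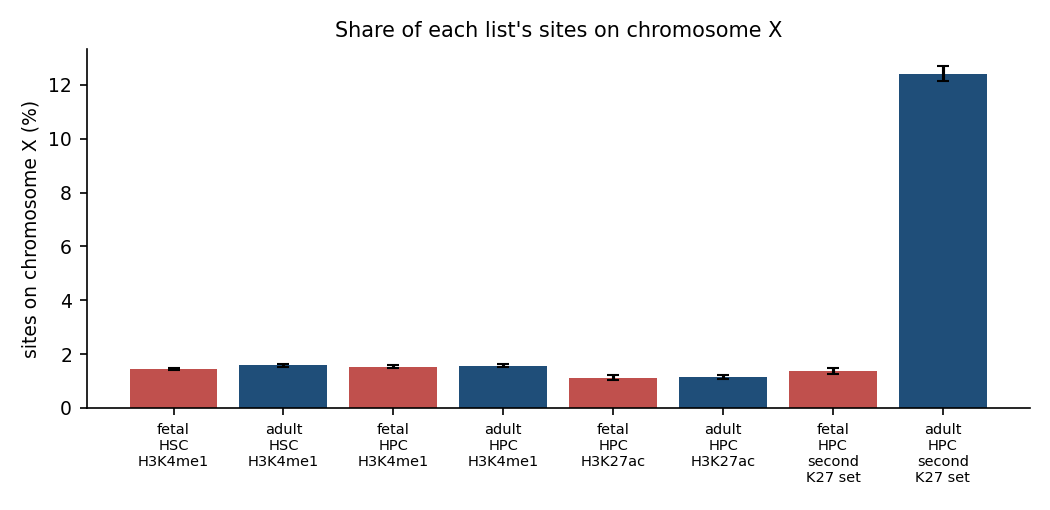
Share of the sites of each of 8 pooled lists that lie on chromosome X (vertical axis, percent), with 95% Wilson intervals, fetal lists in red and adult lists in blue. Over all sites the adult second K27 set stood at 12.4%, and the other lists at 1.12% to 1.58%.

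HSC and HPC of the same age shared almost all of their strongest H3K4me1 sites. In fetal cells, 42 HSC sites (0.210%, 0.155 to 0.284) were not called in HPC and 14 HPC sites (0.070%, 0.042 to 0.117) were not called in HSC. In adult cells the counts were 82 (0.410%, 0.330 to 0.509) and 92 (0.460%, 0.375 to 0.564). Age-only shares of H3K4me1, from 1.31% to 3.04%, were above all 4 of these cell-type shares in the strongest 20000. Over all sites the fetal-only shares stayed above, at 45.0% in HSC and 39.5% in HPC, but the adult-only shares, 22.3% in HPC and 24.9% in HSC, did not, with cell-type shares from 22.6% to 25.3%. The question addressed was how stem cells differ from progenitors within an age.

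The fetal HSC-only sites included 3 at Ctnnal1, alpha-catulin, a marker gene of HSC, and 1 at Mecom, and HSC identity genes held 4 HSC-only and 0 HPC-only sites there (percentile 99.98). The Hox clusters held 1 HSC-only site in fetal cells (percentile 99.2). Adult HSC-only sites included 2 each at Prorp, Boc and Rnf125, 1 at Acacb, an acetyl-CoA carboxylase (fold 11.1), and 1 at Dlk1 (fold 6.36), which placed the imprinted genes at percentile 98.3. Adult HPC-only sites included 2 each at Mrpl46 and Sipa1l2, and 1 each at Mpo, the myeloperoxidase of granulocytes, Il12a, Klf4, Il1a and Ccl3. Inflammatory signalling held 0 HSC-only and 2 HPC-only sites in adult cells, at percentile 1.09. The HSC-minus-HPC difference was 0.140 points (0.068 to 0.219) in fetal cells and -0.050 points (-0.181 to 0.080) in adult cells, the latter within counting error. The other lists lay inside the central 95%. So few sites differed by cell type that 1 site was enough to place the Hox clusters and the imprinted genes outside. Alternatives for gene lists were run for the age comparisons only. With all 4 lists at the shortest length, the fetal difference turned to -0.105 points (-0.239 to 0.027), within counting error. Across alternatives the adult one ran from -1.82 points over all sites to 0.12 points for the strongest 10000.

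**Figure D4:**
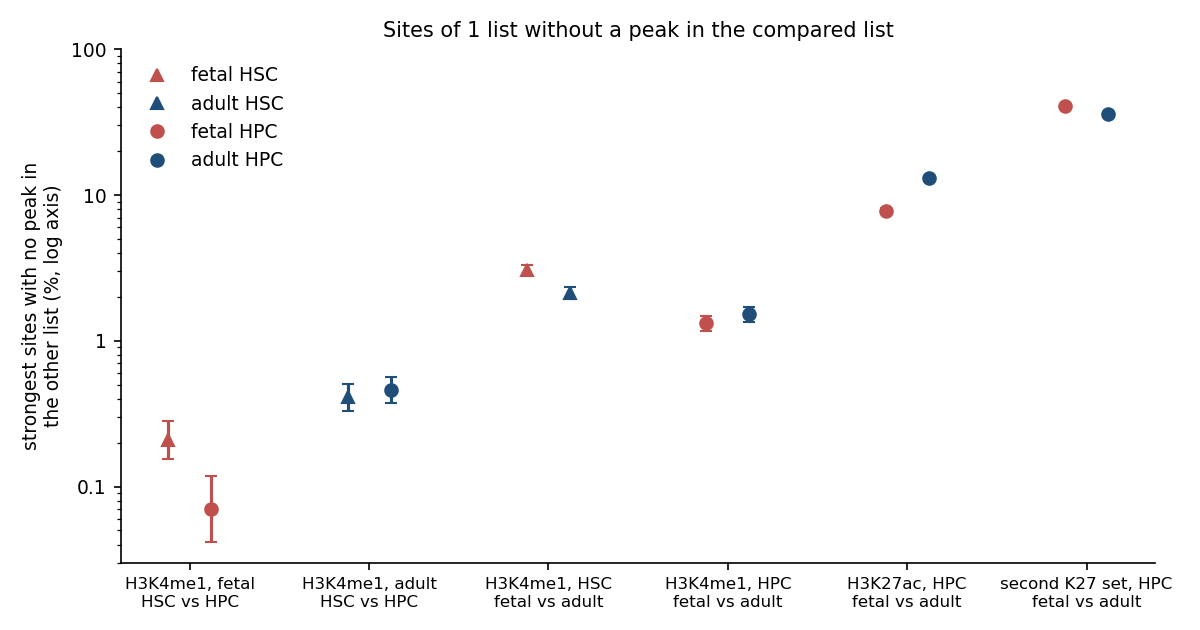
Share of the strongest 20000 sites of each pooled list without a called peak in the compared list (vertical axis, percent, log scale), with 95% Wilson intervals, for 2 comparisons by cell type and 4 by age. H3K4me1 shares by cell type ran from 0.070% to 0.460%, and those by age from 1.31% to 3.04%.

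HSC sites called at 1 age only were called more often in progenitors of the same age than of the other. Of the 609 fetal-only HSC sites, 96.7% (94.98 to 97.9) were called for H3K4me1 in fetal HPC and 39.1% (35.3 to 43.0) in adult HPC. Of the 426 adult-only HSC sites, 96.9% (94.8 to 98.2) were called in adult HPC and 39.9% (35.4 to 44.6) in fetal HPC. Chance overlap was 11.4% to 15.9%. Shared HSC sites were called in HPC lists at 96.3% to 99.9%. The fetal-only HSC sites carried H3K27ac at 23.3% in fetal HPC and 5.91% in adult HPC. The adult-only ones carried it at 53.8% in adult HPC and 7.75% in fetal HPC. With all sites in use the difference between the HPC lists fell to 39.0 points for fetal-only and 31.5 points for adult-only sites, from 57.6 and 57.0. With the HSC lists at equal length it fell to 33.2 points for adult-only sites, of which 65.2% were called in fetal HPC. The HPC lists were not trimmed there.

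Acetylation of the HPC H3K4me1 sites followed the age at which they were called. Of the 263 fetal-only sites, 27.4% (22.3 to 33.1) carried H3K27ac in fetal HPC and 2.66% (1.30 to 5.39) in adult HPC. Of the 303 adult-only sites, 57.1% (51.5 to 62.5) carried it in adult HPC and 5.61% (3.53 to 8.80) in fetal HPC. Shared sites were acetylated more often, at 68.4% in fetal and 86.5% in adult HPC for the strongest sites of the same age. Chance overlap lay between 4.61% and 9.47%. Shared sites were also wider. Their median widths were 3071 bp fetal and 3044 bp adult, against 1518 and 2067 bp of age-only sites, and width was not matched. The comparison asked which H3K4me1 sites were active, and its difference from shared sites was -41.0 points for fetal-only and -29.4 points for adult-only sites. The latter was -19.5 points when an overlap had to cover 50% of the shorter interval.

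Fetal-only H3K4me1 and H3K27ac sites lay away from gene ends more often than adult-only ones. Within 1 kb of a gene end lay 3.4% (2.61 to 4.42) of fetal-only H3K27ac sites and 25.3% (23.7 to 27.04) of adult-only ones, against 39.8% and 43.4% of shared sites. Fetal-only H3K27ac sites lay inside genes at 65.2% (62.8 to 67.5). For H3K4me1 in HSC the shares near gene ends were 2.96% (1.88 to 4.62) fetal-only and 19.2% (15.8 to 23.3) adult-only, against 4.88% and 8.68% of shared sites. In HPC they were 3.04% (1.55 to 5.89) and 15.5% (11.9 to 20.02), against 4.66% and 7.70%. In the second K27 set, 5.06% of fetal-only and 2.31% of adult-only sites lay near a gene end, and 58.8% and 60.4% lay between genes. Gene ends include both the start and the end of each gene, since strand was not used here.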

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

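No paired analysis was possible because the libraries of a group were pooled in 1 list, and for the same reason no library could be left out. The planned motif and exon or intron alternatives were not run. Of 108 alternatives to the main shares and differences, 58 stayed within the main result's interval, 47 moved and 3 reversed. Of 1064 for gene lists, 985 stayed, 58 moved outside and 18 inside the random range, and 3 reversed. Of 2665 for named genes, 1885 stayed within 1.5 times, 737 moved and 43 reversed. Of 140 for single shares, 55 stayed and 85 moved. For values that moved or reversed, the cause was not tested. Leaving out low-fold sites, counting list members and trimming all 4 H3K4me1 lists to the shortest were chosen after seeing the data. List length and unknown depth limit all shares.

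Values are fetal-only minus adult-only shares in percentage points. For H3K4me1 in HSC (0.915) they were 1.66 with 50% overlap, 0.355 within 1 kb, 0.530 at −log10 q of 5, 0.370 for the strongest 10000, 2.74 for 40000 and 20.1 for all sites. They reversed to -2.28 at equal length and to -2.84 with all 4 lists at the shortest. For H3K4me1 in HPC (-0.200) they were 0.135 with 50% overlap, 1.10 for 40000, 17.2 for all sites and -1.46 at both trimmed lengths. For H3K27ac (-5.19) they were -4.39 with 50% overlap, -6.02 within 1 kb, -6.32 at −log10 q of 5, -0.890 for 10000, -11.0 for 40000, -19.4 for all sites, -4.42 at equal length and -2.47 with peaks merged. For the second K27 set (4.67) they were 3.63 within 1 kb, 66.0 at −log10 q of 5 (576 adult sites), 2.28 for 10000, 6.51 for 40000, 7.05 for all sites, 7.86 on autosomes and 3.395 with peaks merged.

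The HSC-only minus HPC-only difference in fetal cells (0.140) was 0.050 at −log10 q of 5, 1.06 for all sites and 0.030 at equal length. It reversed to -0.105 (-0.239 to 0.027) at the shortest, within counting error. In adult cells (-0.050) it was -0.420 at −log10 q of 5, 0.12 for 10000, -0.352 for 40000, -1.82 for all sites and -0.210 at both trimmed lengths. For HSC sites in HPC, the fetal-only difference (57.6) was 61.8 for 40000 and 39.0 for all sites. The adult-only one (57.0) was 47.2 at −log10 q of 5, 31.5 for all sites and 33.2 with the HSC lists at equal length and the HPC lists in full. For acetylation, the fetal-only difference (-41.0) was -29.6 with 50% overlap, and the adult-only one (-29.4) was -19.5 with 50% overlap and -22.9 for 10000. Second-set sites on H3K27ac were 1.05% within 1 kb and 0.352% at −log10 q of 5 in fetal HPC (0.490%), and 0.535% and 0% in adult HPC (0.015%).

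Among gene lists, the myeloid difference changed sign to 42 in HSC H3K4me1 with all sites, and the fetal programme to 7 in the second set at −log10 q of 5. Both settings leave far more fetal-only than adult-only sites among all genes, and the lists lay inside the random range, at percentiles 7.28 and 54.6, so neither sign change is a reversal against matched lists. The myeloid list reversed to 1 in H3K27ac for the strongest 10000 (percentile 98.0). Most sign changes of single genes with all sites or at −log10 q of 5 go with an excess of 1 direction among all sites and say little of the gene. With all sites, Rasgrf1 in HPC H3K4me1 and Ikzf3 in the second set turned against the general excess of fetal-only sites. Rasgrf1 had 4 fetal-only and 9 adult-only sites, and Ikzf3 had 3 and 5. Among named genes, the reversed counts were these numbers of sites in the named direction. For H3K4me1, Sox6 in HSC had 2 for 40000 and 21 for all sites, and Rasgrf1 in HPC had 4 for all sites. For H3K27ac, Hoxa3 had 0 within 1 kb, 0 with peaks merged and 2 for all sites. For 40000, Prdm16 had 7, Rora 13 and Foxo1 1. For all sites, Zfp704 had 12, Dlk1 4, Prdm16 7, Ifitm3 1 and Rora 19. Psmb8 had 1 with every gene within 50 kb. For the second set, Pax2 had 2 within 1 kb, 21 for all sites and 3 with peaks merged. At −log10 q of 5, Ncam1, Ankfn1, Sdk1, Lin28b, Igf2, Ebf1, Rora, Fcgr3, Pax2, Sox14, Apob, Pax5, Cxcl12 and Lepr had 0, Cacna1e 1 and Asic2 3, with 576 adult sites left. Ikzf3 had 2 for 40000, 3 for all sites and 2 within 50 kb. Apob had 2 for 40000, 6 for all sites and 1 with peaks merged. Ndn had 1 for all sites, Sox14 4 ranked by fold and Hoxa13 0 with peaks merged.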

Other observations

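Fetal-only acetylated sites carried H3K4me1 less often than adult-only ones. Of the 1560 fetal-only H3K27ac sites, 66.5% (64.2 to 68.8) were called for H3K4me1 in fetal HPC and 50.1% (47.6 to 52.6) in adult HPC. Of the 2598 adult-only H3K27ac sites, 96.8% (96.0 to 97.4) were called in adult HPC and 86.1% (84.7 to 87.3) in fetal HPC. In HSC, fetal-only sites were called at 68.8% in the fetal and 50.1% in the adult list, and adult-only sites at 79.1% and 94.9%. Shared H3K27ac sites of the fetal list ran from 92.3% to 95.7%, and chance for these classes from 8.27% to 14.98%. Fetal-only H3K27ac sites were narrower, with a median width of 401 bp against 1398.5 bp of adult-only ones. Width was not matched, and an overlap of 1 bp is easier for wider sites.

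The tests of list length and of second-set sites near H3K27ac sites were chosen only after the results were seen, and the others before. Over all its sites, the adult second K27 set held 12.4% on chromosome X. An excess confined to a few loci is argued against, since 104 of 114 bins of 1 Mb (91.2%, 84.6 to 95.2) held more adult than fetal sites. Bins without a site were left out, and how much of the excess each bin held was not tested. Weak calls stay open, since the strongest 2000 adult sites held 2.75% (2.12 to 3.56) on X, between the limits set for the test and above the 0.2% (0.078 to 0.513) of the fetal ones, while at a −log10 q of at least 5 5 of 576 adult sites (0.868%, 0.371 to 2.02) lay there. H3K27me3 on an inactive X may contribute and stays open, since 5 genes that escape X inactivation, 2.40 times 100 kb in all, held 0 adult sites per 100 kb and 328 other X genes with H3K27ac held 2.71, a ratio of 0 with an upper bound of 0.568 from too short a length to decide. Sex of the animals is not named in the labels, and age stays untested as a biological explanation.

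In the strongest 20000 sites, H3K4me1 shares by age were above those by cell type, but over all sites the adult-only share in HPC (22.3%) was below all 4 cell-type shares (22.6% to 25.3%) and the fetal-only shares (39.5% and 45.0%) were above. For the strongest sites, list length alone is argued against. With 126502 sites in each of the 4 lists, the lowest age-only share was 2.12 times the highest cell-type share. The range of 1.88 to 2.39 holds the cell-type share fixed and covers the counting error of the age-only share alone. The lower bound of the age-only share was 1.17%, and the cell-type share was 0.62% with an upper bound of 0.739%. A batch shared within an age cannot be told apart from age, since 0 of 27 libraries had a batch or date in the labels. Age itself may explain the difference in the strongest sites, as an untested hypothesis.

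Fetal-only H3K27ac sites lay near adult-only second-set sites more often than other acetylated sites did. Within 10 kb of such a site lay 1.99% (1.40 to 2.81) of them, against 0.754% (0.639 to 0.889) of shared and 0.539% (0.321 to 0.903) of adult-only H3K27ac sites, and a loss of acetylation with gain of the second mark is a candidate explanation. By the test set, regions rich in second-set sites of either age stay open, since 1.28% (0.831 to 1.97) of the fetal-only sites lay near a fetal-only second-set site, within the intervals. That test left out the shared H3K27ac sites, of which 1.83% (1.64 to 2.03) lay near a fetal-only second-set site. Second-set sites called at both ages were not counted, so these values cannot decide on such regions. In the other direction, 7.35% (6.41 to 8.42) of adult-only H3K27ac sites lay near a fetal-only second-set site, against 1.83% of shared sites. The pattern covers 31 of 1560 sites.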
